A study of Mus musculus with 4 samples.

How the data were processed

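Polyadenylated RNA from the ventricles of 4 adult mouse hearts was sequenced from Illumina TruSeq libraries, per the labels' protocols. The labels name ventricles as the tissue, whereas their extraction protocol speaks of whole hearts. For the submitters' processing, the sources used here name cutadapt 1.2.1, RSEM 1.17, edgeR and the genome build GRCm38, without their roles or order. How the genes of the deposited matrix were chosen is not given in the sources used here. The names of its value columns begin with Norm, which labels the values as normalized, but their unit is not named.

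The matrix pairs 12707 Ensembl gene identifiers with gene symbols and has 4 columns of values. Of these columns, 4 were not used, because their names are codes that match no label of any sample. A search of all sample labels and of the series' design text found 0 of the 4 codes. Neither column order nor expression values were used to assign a column to a heart or a group. While the matrix was being inspected, some of its values were seen to divide the columns into 2 sets, and that division was not used either. The planned tests of genes and gene lists, fixed before the data were examined, were therefore not run, and neither were their alternatives.

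What was computed uses the identifiers and symbols only, with Python 3.11.15 and pandas 2.3.3. Identifiers were matched without version numbers to GENCODE mouse release M21 on GRCm38, which gave the biotypes and coordinates. Of the 12707 identifiers, 125 had no match in it. The matrix gives no symbol for 31 genes. The 46 gene lists were matched by the symbol in the matrix or the annotation's symbol for the same identifier, with an older or newer symbol tried where one had been noted. A gene under yet another symbol would be counted as not listed. The genes named individually are 6 that were fixed beforehand (Myc, Max, Nppa, Nppb, Myh6 and Myh7). The rest of the naming rule ranks genes by test results and could not be applied, so the list members named were chosen after it was known whether they are listed.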

Results

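RNA sequencing was used to profile hearts of adult mice, from tissue labelled as ventricles. In the Myc group, Myc, a transcription factor that drives cell growth, was overexpressed in a mosaic of cardiomyocytes. The labels describe 4 hearts in 2 groups. The Myc group held 2 hearts from mice that carried the iMOS t1-Myc allele together with a tamoxifen-inducible Cre recombinase, MerCreMer, driven in heart muscle. The WT group held 2 hearts from littermates with the same allele and no Cre. All 4 were labelled as 8 weeks of age. Tamoxifen was given in the diet for 4 weeks from weaning, at a labelled dose of 0.5 mg per kg, and hearts were collected 2 weeks after the diet ended. The 2 groups therefore differed in Cre as well as in Myc, and the design held no group with Cre alone.

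The question set by the design was which genes differed between hearts with mosaic Myc overexpression and wild-type hearts. No expression value, fold change or test is reported for this comparison. The deposited matrix has 4 columns of values, and their names are sample codes of which 0 occur in the titles, descriptions, characteristics or protocols of the hearts. No column could be given to a heart or to a group from a label. Columns were not assigned from their order or from the values in them. The level of Myc in each heart and the spread between hearts of a group are not given for the same reason. Agreement between the columns was not computed either, since no value was used. The depth of each library is not given because the columns are named as normalized values.

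The genes that the matrix lists were described without using the values. It lists 12707 genes by Ensembl identifier, of which 12582 were found in the GENCODE mouse release M21 annotation of GRCm38, and 12018 of these are annotated as protein-coding. Myc is among them, as ENSMUSG00000022346, on chromosome 15 from 61985391 to 61990374 on the forward strand of GRCm38. Its dimerisation partner Max is listed as ENSMUSG00000059436, on chromosome 12 from 76937269 to 76962201 on the reverse strand. The natriuretic peptide genes Nppa and Nppb, which are induced in stressed ventricles, are both listed and lie on chromosome 4, from 148000722 to 148002079 and from 147985788 to 147987205. The myosin heavy chain genes Myh6 and Myh7, which encode the main adult and fetal ventricular forms in the mouse, are both listed on chromosome 14, from 54941921 to 54966927 and from 54970684 to 54994626.

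Of 1180 distinct genes in 46 lists fixed before the data were examined, 1043 are listed in the matrix. Some genes, such as Fgf21 and Gdf15, belong to several lists, so the counts per list do not add up to these totals. All 70 genes of the list for ribosome biogenesis and the nucleolus are present, as are all 41 for fatty acid uptake and oxidation. So are all 28 for the tricarboxylic acid cycle and pyruvate entry, and all 30 adult contractile and calcium-handling genes. The list for the nuclear-encoded respiratory chain has 72 of its 73 genes in the matrix, and that for glycolysis and lactate has 25 of 26. The list of negative regulators of hypertrophy has 38 of 42, without Mstn, Ppp1r1a, Fgf21 and Gdf15. The fetal and hypertrophic gene programme has 25 of 26.

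Lists for other cell types were covered unevenly. All 15 fibroblast markers, all 17 endothelial markers and all 13 markers of smooth muscle and pericytes are listed, and so are 24 of 26 macrophage and monocyte markers. For lymphocytes 2 of 17 markers are listed, for neutrophils 0 of 11, and for lung and thymus 0 of 11. Of the 42 genes of the S, G2 and M phases of the cell cycle, 19 are listed, and Ccnb1, Cdk1, Aurkb and Plk1 are among the 23 that are not. The rule that decided which genes the matrix lists is not given in the sources used here. A gene that is not listed is therefore not shown to be unexpressed, and a listed gene is not shown to differ between hearts.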

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

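None of the alternatives planned for the comparison of Myc and WT hearts was run, because no value column could be given to a heart. No paired analysis was possible because the columns carry no replicate number that a label explains. The labels number the hearts of each group 1 and 2 but do not say that these numbers pair them. Only the counts of listed genes could be recomputed, under 2 settings chosen after seeing the data. With each list's own symbols matched to those of the matrix alone, 1037 distinct genes of the fixed lists were found in place of 1043. Older, newer and annotation symbols were not tried in that setting. With the annotation of the reference chromosomes only, 12010 listed genes were protein-coding in place of 12018.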
